A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

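Scanner files of 6 two-channel arrays were read, with precipitated DNA in Cy5 and whole cell extract in Cy3. Per the file headers, the mean, median, background and processed signals are intensity values from Feature Extraction 8.5.1.1. Per the file headers, the LogRatio column holds log10 ratios of the processed signals. The deposited series table holds log2 ratios, which matched the log2 median ratio of the scanner files plus a constant for each array, with column medians of 0.00 to 0.03.

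Before the data were examined, the comparisons, tests, thresholds, gene lists, the rule for named genes and most alternatives were fixed. That design used processed signals, but the wild type files hold 0 in these columns. The log2 ratio was therefore taken from mean signal minus median local background in both channels on all 6 arrays. Each array was centred on its median over 41551 non-control probes, and spots marked as outliers by the scanner software were left out.

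The files name no genome build, so probe sequences were matched to ASM294v3. Of the probes, 40396 had 1 match, 1053 several and 102 none. The mating-type contig (110 probes), of which 36 probes had no match, and the pNSU clones (129 probes) kept the coordinates of the array design. Gene values are means over probes that overlap the gene, with lncRNA genes left out.

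Probes, genes and domains were compared in limma 3.58.1 (R 4.3.3) with 3 groups, 1 pooled spread with 3 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Enriched probes had an adjusted p under 0.05 and a mean log2 ratio of at least 1. Domains were runs of at least 5 probes whose running median over 5 probes, on the mean of the group means, was at least 1, with gaps up to 5 kb joined. They were classed as centromere (within 50 kb), mating-type region (within 20 kb), subtelomere (within 100 kb of an end), pNSU clone or island, and 10 kb bins outside them served the variance prior. Class means were tested by exact permutation and by fry, and the 13 lists by fry and by camera with a preset correlation of 0.01 and an estimated one, over the members measured on all arrays. The lists were Clr6 complexes, heterochromatin machinery, meiotic, mating, Tf2 retrotransposon, stress, histone, marker, iron, zinc and phosphate transport, subtelomeric, hexose transporter, ribosomal protein and tRNA genes. DNA differences between strains were runs of at least 3 probes with a WCE signal 4-fold or more below the other groups.

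Named genes were alp13 and clr6, up to 8 genes per comparison and direction with the largest difference among those that passed with groups that did not overlap (then the next largest, said not to pass), and up to 4 members of each list. Other called genes, the meiotic genes outside this rule and the genes at islands were named after their values were seen.

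Alternatives were normexp background (offset 50), loess, quantile normalization, centring outside domains, scaling to the centromere median, the deposited table, probe and spot filters, replicate and scan-day blocks, another variance prior, other thresholds and gene extents, and leaving out each array. The gene and domain steps were tested on simulated data: of 200 changed genes among 5207, 99% were called at a log2 size of 1 and 100% at 2, with 13 false among 212 calls, and 10 of 10 placed domains were recovered. The gene noise was drawn independently from the variances that limma had fitted, without array effects. These rates therefore check the code and do not say how many real changes would pass. In the data several differences beyond 1 (log2) did not pass. Matching, signals and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.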

Results

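Histone H3 dimethylated at lysine 9 (H3K9me2), the mark that Clr4 places on fission yeast heterochromatin, was mapped by chromatin immunoprecipitation on tiling arrays (ChIP-chip) in 3 genotypes of Schizosaccharomyces pombe, with 2 arrays each. The genotypes were a deletion of alp13, a gene for a chromodomain subunit of a Clr6 histone deacetylase complex, the clr6-1 mutant of the deacetylase itself, and wild type. Each array compared precipitated DNA (Cy5) with whole cell extract DNA (WCE, Cy3) over 41551 probes that tile the genome every 301 bp. The median background-subtracted WCE signal was 775 and 1277 intensity units on the alp13 deletion arrays, 1528 and 663 on the clr6-1 arrays, and 879 and 842 on the wild type arrays. The median WCE spot was 3.24 to 5.91 times as bright as its local background. Values are log2 ratios of ChIP over WCE with the median of each array set to 0, given as mean ± SD over n = 2 arrays. The number of arrays limits the precision. Over all probes the 2 arrays of a genotype correlated at 0.64 (alp13 deletion), 0.59 (clr6-1) and 0.65 (wild type). Pairs from different genotypes ran from 0.33 to 0.78, so replicates were not always the most alike. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between arrays, which may not be that between cultures. In limma the spread of each gene or domain was also drawn toward that of all rows. Its SEs and p-values can therefore overstate the precision of rows that vary more than most, such as heterochromatin domains. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.33.

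The alp13 gene served as a check of the labels. In assembly ASM294v3 it lies on chromosome I at 1587022 to 1588577, and its WCE signal was 7.33% ± 3.24 (SD, n = 2) of the array median in the alp13 deletion, 86.4% ± 1.92 in clr6-1 and 89.6% ± 1.59 in wild type. The clr6 gene, which a point mutation leaves in place, gave 143% ± 4.83 (SD, n = 2), 130% ± 0.83 and 148% ± 0.26 in the same order. The ratio at clr6 differed from wild type by 0.02 ± 0.15 (SE) in the alp13 deletion and by -0.08 ± 0.15 in clr6-1, and between the mutants by 0.09 ± 0.15. clr6 passed the limma test in none of these comparisons. The ratio at alp13 differed between clr6-1 and wild type by -0.19 ± 0.39 (SE) and did not pass. In the alp13 deletion it rests on signals near background, so its differences of -0.31 from wild type and -0.12 from clr6-1 do not measure the mark. The clr6 difference in the alp13 deletion turned to -0.03 after each array was scaled to its centromere median.

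All 3 genotypes carried H3K9me2 at the centromeres, the mating-type region and the chromosome ends. Over the 215 centromere probes the mean log2 ratio was 3.57 ± 0.53 (SD, n = 2) in the alp13 deletion, 3.19 ± 0.74 in clr6-1 and 2.53 ± 0.20 in wild type. The mating-type region, which holds the silent mating-type cassettes, had 2.97 ± 0.79 (SD, n = 2), 1.52 ± 0.46 and 1.77 ± 0.07, and the subtelomeres had 2.41 ± 0.43, 1.62 ± 0.65 and 1.09 ± 0.12. Small domains outside these classes, called islands here, had 2.16 ± 0.17 (SD, n = 2), 1.59 ± 0.45 and 0.87 ± 0.10. The pNSU clones of the array design, of which pNSU71 matched mainly inside chromosome I (20 matches from 3645454 to 3653661), had 1.85 ± 0.01 (SD, n = 2), 1.39 ± 0.24 and 1.45 ± 0.17. Matches of pNSU21, pNSU64, pNSU65 and pNSU70 lay mainly at the right end of chromosome II, from 4535684 on. pNSU77 matched there (9 matches) and on chromosome III (31 matches). On the basis of the mean over genotypes, 23 domains were called: 7 centromere blocks, 5 subtelomeric domains, 2 mating-type domains, 3 islands and 6 pNSU domains.

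**Figure D1:**
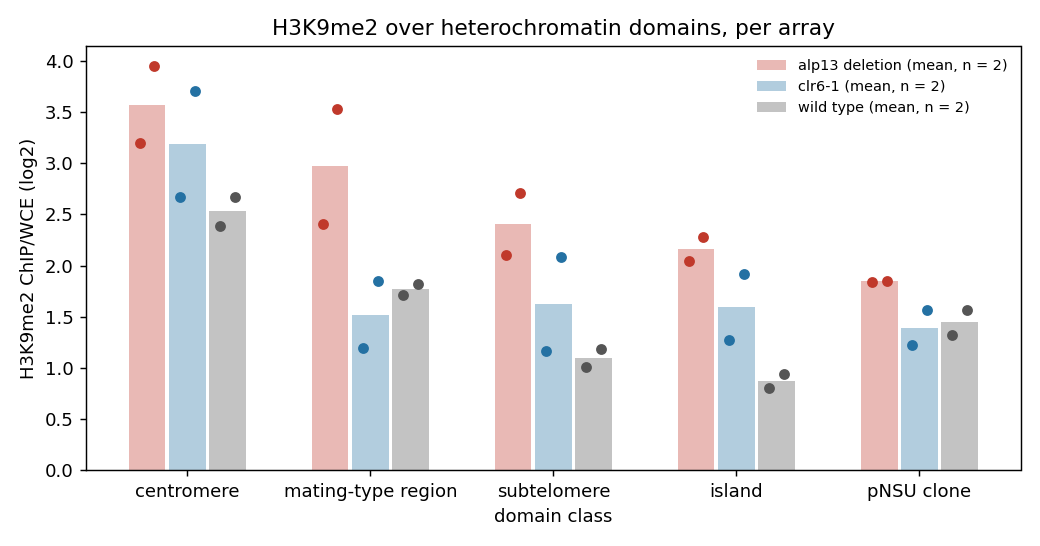
Mean log2 ratio of H3K9me2 ChIP over WCE (y axis) for each class of domain (x axis), with bars for the genotype mean and 1 point per array (n = 2). Subtelomere means are 2.41 in the alp13 deletion, 1.62 in clr6-1 and 1.09 in wild type.

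At a threshold of 2-fold and an adjusted p under 0.05 (limma against the array median), 937 probes were enriched in the alp13 deletion, 923 in clr6-1 and 563 in wild type. Subtelomeric probes made up 297 of these in the alp13 deletion, 209 in clr6-1 and 110 in wild type, and centromere probes numbered 212, 212 and 206 of 215, which leaves no room for an increase to show. Outside all called domains lay 247, 361 and 85. With any 1 array left out, the number of enriched probes ran from 846 to 1245 in the alp13 deletion, from 435 to 1393 in clr6-1 and from 344 to 581 in wild type, so clr6-1 and wild type were not ranked by it. All 3 genotypes shared 495 enriched probes. Domains called on single arrays covered 118 kb ± 4.72 (SD, n = 2) of subtelomere in the alp13 deletion, 95.0 kb ± 52.8 in clr6-1 and 38.8 kb ± 13.1 in wild type. Centromere coverage was 106 kb ± 6.90 (SD, n = 2), 108 kb ± 19.99 and 102 kb ± 2.27. Over the means of each genotype, an island at the malic enzyme gene mae2 (chromosome III, 275621 to 276989) was called in every genotype, islands near cup1 and at 2337987 to 2340227 of chromosome II in both mutants, an island at ssm4 (I, 4534808 to 4535960) in the alp13 deletion and wild type, an island at avl9 (I, 2520754 to 2522093) in the alp13 deletion alone, an island at ura4 (III, 115679 to 116940) in clr6-1 alone, and islands at mei4 (II, 1473208 to 1475048) and at mcp7 (I, 578702 to 580041) in wild type alone. The alp13 deletion lacked DNA at ura4 and could show no island there. At the island of chromosome II without a named gene the wild type ratio was 0.93 ± 0.12 (SD, n = 2), just under the log2 threshold of 1. After scaling to the centromere median, islands called on single arrays covered 7.34 kb ± 2.01 (SD, n = 2) in the alp13 deletion, 6.90 kb ± 0.95 in clr6-1 and 8.17 kb ± 0.21 in wild type. Subtelomere coverage was then 117 kb ± 5.20 (SD, n = 2), 84.25 kb ± 21.01 and 53.05 kb ± 2.68. Such calls compare each genotype with its own background and are no test of a difference.

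The first comparison asked where loss of Alp13 changed H3K9me2 relative to wild type. The mark rose over genes at the chromosome ends. On the right arm of chromosome I, the ratio at SPAC750.01 was 2.74 ± 0.33 (SD, n = 2) in the alp13 deletion and 0.72 ± 0.03 in wild type, and at SPAC186.08C it was 2.64 ± 0.37 and 0.86 ± 0.03. The neighbouring pdc102, a pyruvate decarboxylase gene, had 2.72 ± 0.40 (SD, n = 2) and 0.86 ± 0.19. On the left arm of chromosome I SPAC977.14C had 2.17 ± 0.36 (SD, n = 2) and 0.57 ± 0.05, and on the right arm of chromosome II SPBPB2B2.18 had 2.21 ± 0.08 and 0.51 ± 0.18. The probes of SPBPB2B2.18 all had several matches, so its signal cannot be assigned to this arm alone. The mark fell at meiotic genes inside the chromosome arms: mei4, the gene of a forkhead transcription factor of meiosis, had 0.44 ± 0.01 (SD, n = 2) against 1.39 ± 0.17 in wild type, and mcp7, the gene of a meiotic coiled-coil protein, had 0.08 ± 0.14 against 1.21 ± 0.11.

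limma called 17 of 5237 genes, 15 higher and 2 lower, and in all 17 both alp13 deletion arrays lay on the same side of both wild type arrays. Groups did not overlap for 40.7% of genes tested, against 33.3% by chance. The log2 difference was 2.02 ± 0.23 (SE) at SPAC750.01 (limma adjusted p = 0.0128), 1.86 ± 0.26 at pdc102 (adjusted p = 0.0251) and 1.78 ± 0.20 at SPAC186.08C (adjusted p = 0.0128). The other genes with the largest increases were SPBPB2B2.18 (1.70), ftm3 (1.64), SPAC977.14C (1.60), ftm7 (1.60) and ftm2 (1.4967). Of the 15 genes that rose, 14 lay within 100 kb of a chromosome end, as 205 of the 5237 tested genes did (Fisher's exact test, two-sided, p = 1.86e-19). The remaining gene was cup1 on chromosome II, with a log2 difference of 1.15 ± 0.14 (SE, limma adjusted p = 0.0128). Neighbouring genes are not independent in that Fisher test. ftm2, ftm3, SPBPB2B2.16C and SPBPB2B2.18 had only probes with several matches, so copies of a sequence may count there as separate genes. Over probes with 1 genomic match limma called 11 genes higher and 2 lower. mcp7 fell by 1.13 ± 0.14 (SE, limma adjusted p = 0.0161) and mei4 fell by 0.95 ± 0.14 (adjusted p = 0.0286) on the log2 scale, and ssm4, the third meiotic gene with a peak in wild type, differed by -0.57 ± 0.15 (adjusted p = 0.324) and did not pass. The next largest decreases among genes whose groups did not overlap, which did not pass, were the 5S rRNA gene SPRRNA.04 (-1.10), tom5 (-1.06), SPAPB18E9.05C (-0.97), SPNCRNA.115 (-0.93), and the tRNA genes SPATRNAILE.02 (-0.93) and spl1 (-0.93). With either wild type array left out, 0 genes passed in limma (347 without the first and 139 without the second at an unadjusted p under 0.05). Without the second alp13 deletion array the balance turned around, with 12 genes higher and 22 lower. limma also called 0 genes with loess within arrays or with a variance trend and robust prior (315 and 436 at an unadjusted p under 0.05), and 1 with lncRNA genes included.

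**Figure D2:**
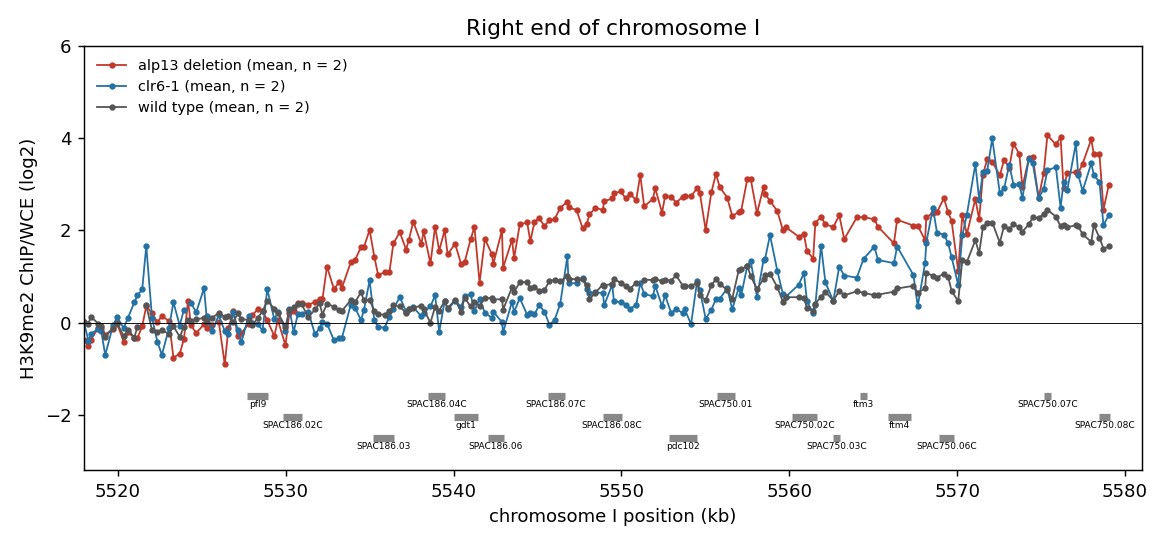
Log2 ratio of H3K9me2 ChIP over WCE (y axis, mean of 2 arrays per genotype, 1 point per probe) along the right end of chromosome I in kb (x axis, ASM294v3), with protein-coding genes as grey bars. At SPAC750.01 the means are 2.74 in the alp13 deletion, 0.52 in clr6-1 and 0.72 in wild type.

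Of the 23 domains 2 passed. The domain at the right end of chromosome I (5543608 to 5579096) had a mean ratio of 2.599 ± 0.418 (SD, n = 2) in the alp13 deletion and 1.11 ± 0.13 in wild type, a difference of 1.49 ± 0.24 (SE, limma adjusted p = 0.0402). The SD at this domain was 0.536 in clr6-1. limma drew the pooled spread toward that of the bins outside domains, so this SE is smaller than the arrays alone give. Called on the mean of its own arrays, this domain reached inward to 5533876 in the alp13 deletion, over a length of 45.2 kb. The island near cup1 (II, 2197733 to 2199886) had 2.21 ± 0.06 (SD, n = 2) against 0.33 ± 0.09, a difference of 1.88 ± 0.13 (SE, limma adjusted p = 0.000134). One of these 2 calls was lost with loess, with outlier spots kept, on the deposited table, with crossed replicate numbers, and without the second alp13 deletion array or either wild type array. The other 21 domains did not pass, among them the chromosome end domains I left (1.15 ± 0.30 SE, adjusted p = 0.179), II left (1.40 ± 0.29, adjusted p = 0.119), II right (1.41 ± 0.26, adjusted p = 0.0805) and III left (0.59 ± 0.15, adjusted p = 0.179). Over classes of probes, shifts did not pass for the subtelomeres (1.31, fry adjusted p = 0.125), the mating-type region (1.20, fry adjusted p = 0.125), the centromeres (1.04, fry adjusted p = 0.142) and the pNSU clones (0.40, fry adjusted p = 0.125). The 3 islands called on the mean over genotypes had a shift of 1.29 (fry adjusted p = 0.0422), a call lost in 12 of 26 alternatives. That choice of islands took in the one near cup1 and left out those at mcp7, mei4 and ssm4, which were called in wild type, so the shift is no measure of islands at large. The exact permutation test gave p = 0.33 for each of these 5 class means. The subtelomere probes were likewise chosen on the mean over genotypes. Called on the mean of each genotype, subtelomeric domains covered 114.4 kb in the alp13 deletion, 89.8 kb in clr6-1 and 34.2 kb in wild type. That choice takes in stretches enriched in the mutants only, which can raise the subtelomere shift. After each array was scaled to its own centromere median, the subtelomere shift was 0.78 (fry adjusted p = 0.0289) and the centromere shift 0.06. Of the 215 centromere probes 93 were saturated on the second alp13 deletion array, against 0 and 1 on the wild type arrays, which compresses the centromere values, and scaled on probes saturated on no array the subtelomere shift was 0.80 and did not pass (fry adjusted p = 0.0524). After scaling on all centromere probes the pNSU shift turned to -0.11 (fry adjusted p = 0.562). limma then called 8 domains. Higher were the chromosome end domains I left (0.57, limma adjusted p = 0.00435), I right (0.93), II left (0.9994) and II right (0.98), the mating-type domain of chromosome II (0.49, adjusted p = 0.0172) and the islands near cup1 (1.56) and at mae2 (0.56, adjusted p = 0.0179), and lower was pNSU70 (-0.42, adjusted p = 0.00614). Quantile normalization turned the centromere shift to -0.14. At the level of single probes, 35 of 41338 were higher and 0 lower in limma, with 3092 at an unadjusted p under 0.05, and 28 of the 35 lay within 100 kb of a chromosome end. Without the second alp13 deletion array 14 probes were higher and 97 lower. Both wild type arrays were scanned on a day without mutant arrays, so scan day and genotype cannot be told apart here.

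Of 20 measured meiotic genes, 2 fell, 0 rose and 18 did not pass, and adjusted over the list alone 3 fell (mcp7, ssm4 and mei4). fry, whose p-value tests whether the genes of a list move one way on balance and does not compare them with other genes, gave an adjusted p of 0.0126 for this list, and camera 0.0673. The median difference of the meiotic list was -0.03, with 10 of 20 genes below 0. Among 13 Tf2 retrotransposon genes none passed, over all genes or adjusted over the list alone, and the largest differences were Tf2-7 (0.41), Tf2-9 (0.37), Tf2-11 (0.37) and Tf2-10 (0.25). The median difference of the Tf2 genes was 0.17 (camera adjusted p = 0.0363, and adjusted p = 0.251 with an estimated correlation), and it turned negative with loess (-0.47), with normexp background (-0.11) and with quantile normalization (-0.02). Tf2-7, Tf2-9 and Tf2-10 had no probe with 1 genomic match, so their signals cannot be assigned to single elements. In every comparison, members of this list may therefore count the same sequence more than once. None of 131 ribosomal protein genes passed in either count, and their median difference was -0.15, with rpl4102 (-0.64) and rps7 (-0.63) as examples (camera adjusted p = 1.37e-05, and adjusted p = 0.251 with an estimated correlation). Of 16 measured tRNA genes 0 passed over all genes and 6 fell adjusted over the list alone, with a median of -0.45 (camera adjusted p = 3.33e-05, and adjusted p = 0.251 with an estimated correlation). No list call of camera held with an estimated correlation, in this or either other comparison.

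The remaining lists of this comparison passed in neither version of camera. Among 15 mating genes 0 passed over all genes, and mat1-Mc (1.48) and mat3-Mc (1.22), the genes of the M mating type, were higher adjusted over the list alone (list median 0.03). Neither mat1-Mc nor mat3-Mc had a probe with 1 genomic match, so their signals cannot be assigned to a single cassette. The telomere-linked helicase gene tlh1, the only measured member of the subtelomeric list, had a difference of 1.26 ± 0.32 (SE, limma adjusted p = 0.244), and it passed adjusted over the list alone. tlh1 had no probe with 1 genomic match either, so its signal cannot be assigned to a single chromosome end. No member passed in either count among 10 genes of the Clr6 complexes (median -0.05, prw1 0.45), 25 of the heterochromatin machinery (0.08, cid14 0.33), 17 stress genes (0.01, obr1 0.38), 11 histone genes (-0.17, hht2 -0.44), 13 marker loci (0.03, his1 0.41), 11 genes of iron, zinc and phosphate transport (-0.11, pho1 -0.40, or 0.02 with normexp background) and 8 hexose transporter genes (-0.09, ght3 -0.42). Their camera adjusted p ran from 0.0673 for the histone genes to 0.921 for the marker loci. fry gave an adjusted p of 0.0126 for the Tf2 and for the histone genes and of 0.0288 for the transport genes. Of its 4 list calls only the meiotic one held after scaling to the centromere median, and with 1 array left out 0 to 3 lists passed in fry. The median and the mean difference had opposite signs for the stress genes (0.01 and -0.02) and the marker loci (0.03 and -0.04). The marker loci include ura4, whose DNA the alp13 deletion lacks, so its difference there (-0.78, or 0.08 with loess) rests on signals near background and does not measure the mark.

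The second comparison set the deacetylase mutant clr6-1 against wild type. The mark fell at the same kind of meiotic gene. mei4 had a ratio of -0.00 ± 0.10 (SD, n = 2) in clr6-1 against 1.39 ± 0.17 in wild type, ssm4, the gene of a meiotic dynactin subunit, had 0.09 ± 0.01 against 1.29 ± 0.08, and mcp7 had 0.06 ± 0.05 against 1.21 ± 0.11. No gene at the chromosome ends passed the test in clr6-1. Means above wild type were found at SPBC1348.15 at the left end of chromosome II (difference 1.24 ± 0.36 SE) and SPAC212.03 and SPAC212.04C at the left end of chromosome I (1.15 ± 0.34 and 1.12 ± 0.29). All 35 probes of the domain at II left and 107 of 125 at I left had several matches. These increases can therefore not be assigned to 1 end each, and copies of a sequence may count as separate genes. Means below wild type, with a large spread between the clr6-1 arrays, were found at pdc102 (0.31 ± 0.55 SD, n = 2, against 0.86 ± 0.19 in wild type), SPAC186.08C (0.43 ± 0.28 against 0.86 ± 0.03), SPAC977.14C (0.31 ± 0.25 against 0.57 ± 0.05) and SPAC750.01 (0.52 ± 0.49 against 0.72 ± 0.03).

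limma called 3 of 5235 genes, 0 higher and 3 lower, with both clr6-1 arrays below both wild type arrays at each. mei4 fell by 1.40 ± 0.14 (SE, limma adjusted p = 0.0134), ssm4 fell by 1.20 ± 0.15 (adjusted p = 0.0318) and mcp7 fell by 1.15 ± 0.14 (adjusted p = 0.0318) on the log2 scale. ubp8, which overlaps the 3' end of mcp7 on the other strand, differed by -0.89 ± 0.15 (SE, limma adjusted p = 0.178), and sks2 (-0.88), dap1 (-0.83), snu3 (-0.80) and tef103 (-0.79) did not pass either. Among the largest increases none passed: SPAC1F3.08C (2.53 ± 0.55 SE), SPBCPT2R1.01C (1.03 ± 0.32), ura4 (1.02 ± 0.71), SPAC212.01C (0.97 ± 0.32) and SPNCRNA.450 (0.95 ± 0.39). In the domain at II right, which holds SPBCPT2R1.01C, 29 of 30 probes had several matches, so the limit on repeated sequences holds there too. Groups did not overlap for 38.4% of genes, against 33.3% by chance. Of 41321 probes 0 passed in limma, with 2182 at an unadjusted p under 0.05. No gene passed in limma without the first or the second wild type array, without the second clr6-1 array, or with a variance trend and robust prior (208, 116, 160 and 317 at an unadjusted p under 0.05), nor with lncRNA genes included. Without the first clr6-1 array 30 genes passed, 19 higher and 11 lower, and 435 to 1393 probes were enriched on single clr6-1 arrays.

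**Figure D3:**
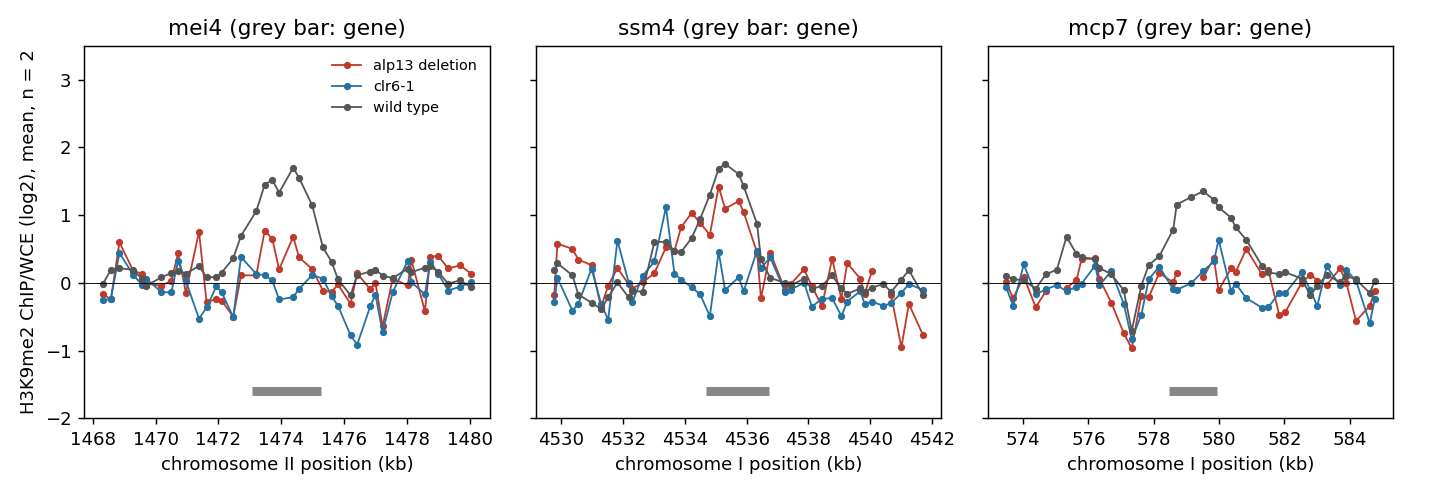
Log2 ratio of H3K9me2 ChIP over WCE (y axis, mean of 2 arrays per genotype, 1 point per probe) around mei4, ssm4 and mcp7, along the chromosome in kb (x axis, ASM294v3). Gene means are 1.39, 1.29 and 1.21 in wild type, 0.44, 0.71 and 0.08 in the alp13 deletion, and -0.00, 0.09 and 0.06 in clr6-1.

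Of the 23 domains, the island near cup1 passed with a difference of 0.97 ± 0.13 (SE, limma adjusted p = 0.0260), from 1.30 ± 0.34 (SD, n = 2) in clr6-1 and 0.33 ± 0.09 in wild type. This call was lost with loess, with a variance trend and robust prior, with crossed replicate numbers, and without either alp13 deletion array or either wild type array. The right end of chromosome I differed by 0.20 ± 0.24 (SE, limma adjusted p = 0.906). Class shifts did not pass: 0.66 for the centromeres, -0.25 for the mating-type region, 0.53 for the subtelomeres and -0.05 for the pNSU clones (fry adjusted p = 0.589 for each), and 0.72 for the islands (fry adjusted p = 0.183). The exact permutation p was 0.67, 1, 0.67, 0.67 and 0.33 in this order. After scaling to the centromere median the mating-type shift was -0.68 (fry adjusted p = 0.0515), the subtelomere shift 0.21 (fry adjusted p = 0.274) and the pNSU shift -0.39 (fry adjusted p = 0.158). The mating-type class includes 13 probes without DNA in clr6-1, and without these its shift was -0.04 (fry adjusted p = 0.863), or -0.49 after scaling (fry adjusted p = 0.103). limma called 4 domains after scaling: the island near cup1 (0.86) and III left (0.51, limma adjusted p = 0.0448) were higher, and the mating-type domains of chromosome II (-0.56, adjusted p = 0.0120) and of the contig (-0.75), which holds the probes without DNA, were lower. Scan day and genotype cannot be told apart in this comparison either.

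Of 20 measured meiotic genes, 3 fell, 0 rose and 17 did not pass, and adjusted over the list alone 4 fell (mcp7, ssm4, num1 and mei4). The list median was -0.14 (camera adjusted p = 0.00048, and adjusted p = 0.138 with an estimated correlation). Ribosomal protein genes had no member past the threshold in either count, with a median of -0.22, rpl902 (-0.78) and rpl1502 (-0.71) as examples, and 106 of 131 below 0 (camera adjusted p = 6.21e-11, and adjusted p = 0.138 with an estimated correlation). No tRNA gene of 16 passed in either count, with a median of 0.25 and spl1 as an example (0.57, or -0.13 with normexp background) (camera adjusted p = 0.00429, and adjusted p = 0.276 with an estimated correlation). fry gave an adjusted p of 0.0103 for the meiotic genes, 0.0148 for the Tf2 genes, 0.0301 for the transport genes and 0.0484 for the ribosomal protein genes. Of these 4 only the meiotic call held after scaling to the centromere median, and with 1 array left out 0 to 2 lists passed in fry.

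The other lists had no member past the threshold in either count and did not pass in camera. Median differences were -0.13 for the 13 Tf2 genes (Tf2-5, -0.26), -0.10 for the Clr6 complexes (cph1, 0.22), 0.08 for the heterochromatin machinery (sir2, 0.29), 0.03 for the mating genes (mfm2, 0.37) and -0.02 for the stress genes (gpx1, -0.53). They were -0.08 for the histone genes (hht2, -0.58), 0.01 for the marker loci (ura4, 1.02), -0.07 for the transport genes (pho1, -0.55) and -0.13 for the hexose transporter genes (ght2, -0.32). The difference at tlh1 was 0.59 ± 0.32 (SE, limma adjusted p = 0.828), and it was -0.04 with quantile normalization. Camera adjusted p ran from 0.0672 for the Tf2 genes and the heterochromatin machinery to 0.766 for the marker loci, where its direction (down) was opposite to the median and the mean.

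Both comparisons used the same wild type arrays. mcp7 and mei4 fell in both, 2 genes against 0.0011 for independent lists and a mean of 0.03 (at most 1) in 100 simulations of unchanged groups against the shared arrays. No gene rose in both, where these simulations gave a mean of 0.02 (at most 2). So 2 genes shared in 1 direction also arose with no effect. Across 5235 genes, which are not independent replicates, the differences correlated with r = 0.367, and the simulations with no effect gave 0.5002. That simulated value belongs to groups of equal spread. The SD of the difference between replicate arrays was 0.3054 in wild type, 0.4999 in the alp13 deletion and 0.4909 in clr6-1. A smaller spread in the shared wild type arrays lowers the correlation that arises with no effect, so the observed one was not ranked against 0.5002. The covariance was 0.0194 against a simulated 0.0139, with the same limit. With 1 array in each part, the wild type arrays were too few to be split, and the error of the shared arrays enters both lists.

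The third comparison set the alp13 deletion directly against clr6-1, without the wild type arrays in the difference. The mark was higher in the alp13 deletion over a block of genes inside the right end of chromosome I. pdc102 had 2.72 ± 0.40 (SD, n = 2) in the alp13 deletion and 0.31 ± 0.55 in clr6-1, SPAC750.01 had 2.74 ± 0.33 and 0.52 ± 0.49, and SPAC186.07C had 2.32 ± 0.34 and 0.14 ± 0.07. On the left arm SPAC977.14C had 2.17 ± 0.36 (SD, n = 2) and 0.31 ± 0.25. Lower values in the alp13 deletion were found at small nucleolar RNA genes: snoU14 had -0.95 ± 0.37 (SD, n = 2) against 0.35 ± 0.25, snR10 had -0.87 ± 0.28 against 0.29 ± 0.12, and snR41 had -0.50 ± 0.03 against 0.56 ± 0.08.

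limma called 13 of 5235 genes, 9 higher and 4 lower in the alp13 deletion, and in all 13 the arrays of the 2 genotypes did not overlap. The log2 difference was 2.41 ± 0.26 (SE) at pdc102 (limma adjusted p = 0.00433), 2.21 ± 0.20 at SPAC186.08C and 2.18 ± 0.18 at SPAC186.07C (adjusted p = 0.00185 for both). The others that rose were SPAC750.01 (2.23), SPAC977.14C (1.86), SPAC186.04C (1.4998), SPAC186.03 (1.25), gdt1 (1.18) and SPBPB21E7.09 (1.14), and all 9 lay within 100 kb of a chromosome end (Fisher's exact test, two-sided, p = 1.83e-13). Most of the 9 lie in 1 block at the right end of chromosome I. Neighbouring genes are not independent in this Fisher test either, so its p-value overstates the evidence. The genes that fell were snoU14 (-1.30 ± 0.19 SE, limma adjusted p = 0.0292), snR10 (-1.16 ± 0.17, adjusted p = 0.0244), snR41 (-1.07 ± 0.13, adjusted p = 0.0106) and SPBC887.16 (-1.04 ± 0.16, adjusted p = 0.0414), each measured by 1 probe. Among decreases without overlap between the arrays of the 2 genotypes, the largest that did not pass were SPAC1F3.08C (-2.76), spl1 (-1.50), SPRRNA.29 (-1.22) and SPRRNA.03 (-1.14). Of 41210 probes, 64 were higher and 34 lower, and 4485 had an unadjusted p under 0.05. limma with loess within arrays, and limma on the processed signals of the scanner software, each called 2 genes. Without the second alp13 deletion array 13 genes were higher and 58 lower, and without the first clr6-1 array 7 were higher and 9 lower.

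At the right end of chromosome I the domain mean differed by 1.29 ± 0.24 (SE, limma adjusted p = 0.0574), and only the island near cup1 passed among the 23 domains (0.91 ± 0.13 SE, adjusted p = 0.0212). That call was lost with loess, with crossed replicate numbers, on the processed signals, and without either alp13 deletion array or either wild type array. The mating-type domains differed by 1.34 ± 0.30 (SE, limma adjusted p = 0.0745) on chromosome II and by 1.52 ± 0.32 (adjusted p = 0.0666) on the mating-type contig of the array design. Class shifts were 0.38 for the centromeres, 1.45 for the mating-type region, 0.79 for the subtelomeres, 0.57 for the islands and 0.45 for the pNSU clones (fry adjusted p = 0.533, 0.146, 0.230, 0.172 and 0.146, and exact permutation p = 0.67, 0.33, 0.33, 0.33 and 0.33). One array of each mutant shared a scan day, and between these the differences were -0.51, 0.56, 0.03, 0.13 and 0.28 in the same order, so the subtelomere and island shifts were near 0 within that day. After scaling to the centromere median the mating-type shift was 1.11 and passed (fry adjusted p = 0.0143), and the subtelomere shift was 0.56 and did not (fry adjusted p = 0.0800), nor did the pNSU shift of 0.28 (fry adjusted p = 0.242). Without the 13 probes that lack DNA in clr6-1 the mating-type shift was 1.22 (fry adjusted p = 0.173), or 0.91 after scaling (fry adjusted p = 0.0327). limma called 6 domains after scaling, all higher in the alp13 deletion: I right (1.03), II right (0.65, limma adjusted p = 0.00402), II left (0.51, adjusted p = 0.0441), the mating-type domains of chromosome II (1.04) and of the contig (1.15), and the island near cup1 (0.70).

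Of the fixed lists, the Tf2 genes had a median difference of 0.27 (0.0032 with loess and 0.12 with normexp background), with 0 of 13 past the threshold over all genes and 2 higher (Tf2-7 and Tf2-11) adjusted over the list alone (camera adjusted p = 0.000345, and adjusted p = 0.144 with an estimated correlation). Tf2-7 and Tf2-11 differed by 0.56 and 0.52, and by -0.12 and -0.16 on the processed signals of the scanner software. Tf2-7 had no probe with 1 genomic match, so its signal cannot be assigned to a single element. The 16 tRNA genes had a median of -0.78, with 0 past the threshold over all genes and 10 lower adjusted over the list alone, among them spl1 (-1.50) and SPATRNAALA.06 (-0.95) (camera adjusted p = 3.17e-09, and adjusted p = 0.144 with an estimated correlation). Within the shared scan day the mean difference was -0.74 for the tRNA genes and 0.25 for the Tf2 genes. fry gave an adjusted p of 0.0038 for the Tf2 genes and of 0.0482 for the tRNA genes and for the meiotic genes, whose median was 0.11 with 0 of 20 past the threshold (ssm4, 0.62). None of these 3 fry calls held after scaling to the centromere median, and with 1 array left out 0 to 2 lists passed. Among 15 mating genes 0 passed over all genes, and adjusted over the list alone mat1-Mc (1.66) and mat3-Mc (1.48) were higher and mam4 (-0.60) and mfm2 (-0.53) lower. Their median was -0.03 and their mean 0.08.

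The other lists had no member past the threshold in either count and did not pass in camera, with adjusted p from 0.273 for the histone genes to 0.979. Median differences were -0.02 for the Clr6 complexes (pst3, 0.39), 0.03 for the heterochromatin machinery (tas3, 0.41), 0.01 for the stress genes (obr1, 0.76), -0.15 for the histone genes (hht3, -0.29) and -0.02 for the marker loci (ura4, -1.80, which rests on signals near background in the alp13 deletion and does not measure the mark). They were 0.02 for the transport genes (str3, -0.42), 0.05 for the hexose transporter genes (ght3, -0.41) and 0.07 for the ribosomal protein genes (rpl35A01, -0.76). The difference at tlh1 was 0.67 ± 0.32 (SE, limma adjusted p = 0.492), and -0.20 between the arrays that shared a scan day. Median and mean had opposite signs for the Clr6 complexes, the transport genes and the hexose transporter genes (means 0.05, -0.01 and -0.02), and camera gave the opposite direction (up) to both for the marker loci.

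The WCE channel showed which DNA each strain carried. In the alp13 deletion the probes of alp13 (I, 1587466 to 1588303) and of the marker gene ura4 (III, 116002 to 116940) differed from the mean of the other genotypes by -4.25 and -4.04 on the log2 scale. In clr6-1 a stretch of the mating-type contig from 25201 to 28560, with 12 probes, had a mean WCE signal of -4.85 against 0.47 in the other genotypes. The wild type strain lacked signal over 3 stretches of chromosome I between 2931765 and 2939632, which include cao1 and cbm1. Over the 12 contig probes the ratio was 3.24 ± 1.09 (SD, n = 2) in the alp13 deletion, 0.70 ± 0.44 in clr6-1 and 1.94 ± 0.10 in wild type, where the clr6-1 value rests on signals near background. A single further probe of that domain (from 31201) had a WCE signal of -3.97 in clr6-1. Over the 40 probes with DNA in every genotype the ratio was 3.01 ± 0.77 (SD, n = 2), 1.87 ± 0.69 and 1.83 ± 0.07. Signals near background make the WCE differences lower bounds of the loss, except at ura4. There the mean of the other genotypes includes clr6-1 (0.44 and 0.75 on its arrays), which lay above wild type (-0.93 and -0.86). The stretches were chosen by the 4-fold rule on runs of at least 3 probes.

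**Figure D4:**
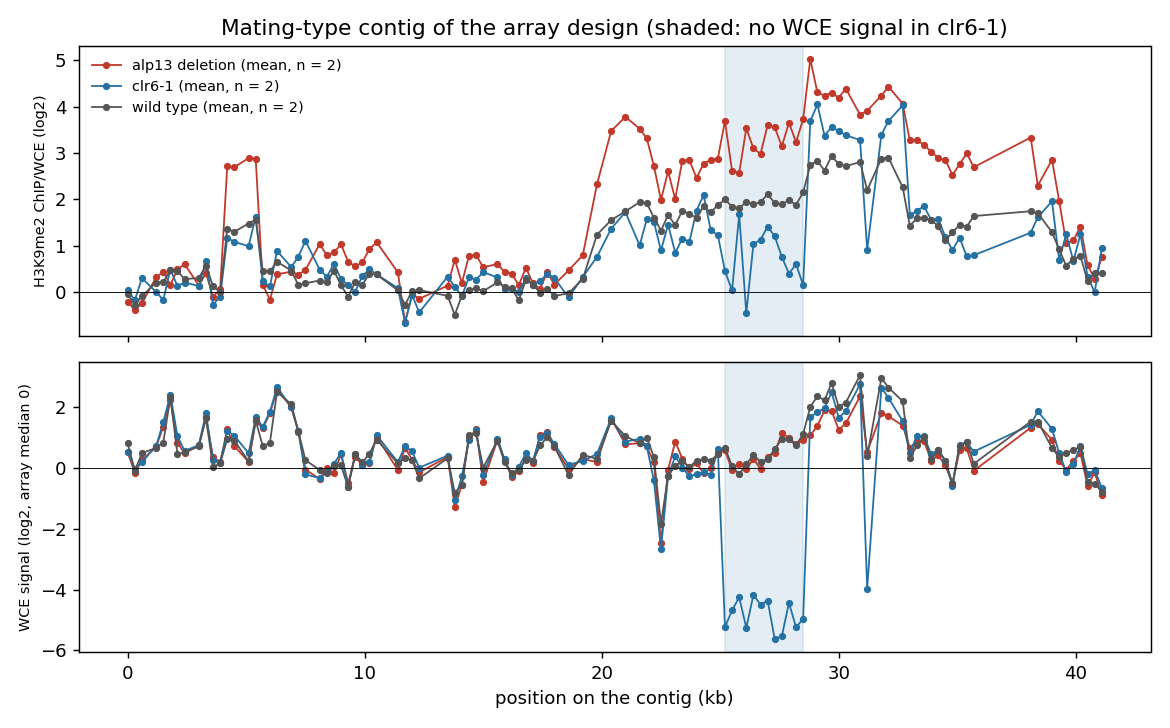
Log2 ratio of H3K9me2 ChIP over WCE (upper y axis) and log2 WCE signal with the array median at 0 (lower y axis) along the mating-type contig of the array design in kb (x axis), as means of 2 arrays per genotype with 1 point per probe. In the shaded stretch the mean WCE signal is -4.85 in clr6-1, 0.46 in the alp13 deletion and 0.49 in wild type.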

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

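Among the tests of causes below, only the WCE difference at mei4, ssm4 and mcp7 was chosen for that use before its result was seen. All others were chosen for that use after. Scaling to the centromere median and the restriction to uniquely matched probes had been planned, but as processing alternatives. With 2 arrays per genotype, none was tested for lying far from the others of its group.

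The WCE channel, which serves as the reference of the ratio, showed signal near background where a strain lacked DNA. Relative to the other genotypes, it was lower by a log2 difference of -4.25 in the alp13 deletion at alp13 (I, from 1587466), by -4.04 in the alp13 deletion at ura4 (III, from 116002) and by -5.33 in clr6-1 on the mating-type contig (from 25201). In wild type it differed by -3.97, -4.45 and -3.63 on chromosome I from 2931765, 2933135 and 2937411. Since the lower signals lay near background, these sizes are lower bounds, except at ura4, where the reference includes the raised signal of clr6-1.

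A test of the difference between both mutants singled out genes and a domain whose change from wild type was not the same in both. Toward the alp13 deletion these were SPAC186.03 (1.25), SPAC186.04C (1.4998), gdt1 (1.18), SPAC186.07C (2.18), SPAC186.08C (2.21), pdc102 (2.41), SPAC750.01 (2.23), SPAC977.14C (1.865), SPBPB21E7.09 (1.14) and the island near cup1 (0.91). Toward clr6-1 they were SPBC887.16 (-1.04), snR41 (-1.07), snoU14 (-1.30) and snR10 (-1.16).

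The first pattern weighed was the higher ratio over subtelomeric domains in the alp13 deletion than in wild type. For stronger immunoprecipitation or a wider ratio scale as the whole cause, scaling to the centromere median left a shift of 0.7757 (fry adjusted p = 0.0289). On centromere probes saturated on no array the shift of 0.7994 had an adjusted p of 0.0524 and met only the bound set on the unadjusted test. Mitochondrial probes, which lie in no domain class, shifted by 0.6472 unscaled and by 0.7177 after scaling (fry unadjusted p = 0.0340 and 0.0594). Scaling thus left a difference of similar size outside heterochromatin. The subtelomere probes were also chosen on a mean that includes the alp13 deletion, which can raise their shift. The test therefore cannot settle this cause. Cross-hybridisation of repeated probes was argued against by a shift of 1.4967 over probes with 1 genomic match (fry adjusted p = 0.0403), but only where such probes lie. They lie mainly at I right, where 57 of 110 probes had several matches, against 107 of 125 at I left. Several matches were found for 35 of 35 probes at II left, 29 of 30 at II right and 8 of 8 at III left. For these 3 ends the test cannot decide. Matches were exact, so near copies of a probe sequence were not counted. Scan day stayed open, since 0 scan days held arrays of both groups, so that batch and genotype cannot be told apart. An effect of the mutation also stayed open and was not tested separately.

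The second pattern was the lower ratio at mei4, ssm4 and mcp7 in both mutants than in wild type. Weaker immunoprecipitation as the whole cause was argued against by the centromere medians, which it would lower as well. Over the 3 genes the mean log2 ratio was 0.4108 in the alp13 deletion, 0.0482 in clr6-1 and 1.2962 in wild type. As quotients of these log2 values the mutants stood at 0.3169 and 0.0372 of wild type. The lowest centromere median log2 ratio stood at 1.2135 and 1.0384 times the wild type mean, with the wild type arrays 0.1022 apart. These quotients are of log2 values and are not shares of the ChIP over WCE ratio itself. A different amount of DNA was argued against by WCE differences of -0.0041 and -0.0121 over these genes. Scan day or another batch of the wild type arrays stayed open, since 0 scan days held wild type and a mutant. An effect of the mutations stayed open as well.

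The third pattern was the lower ratio over the mating-type region in clr6-1 than in the alp13 deletion. Missing DNA under the probes as the whole cause was argued against by a scaled shift of 0.9369 without these probes (fry adjusted p = 0.0276), although unscaled it was 1.2456 and did not pass (fry adjusted p = 0.173). A single probe without DNA escaped that choice, and with it left out as well the scaled shift was 0.9108 (fry adjusted p = 0.0327). For weaker immunoprecipitation in clr6-1, scaling left a shift of 1.1119 (fry adjusted p = 0.0143), which includes the probes without DNA. Mitochondrial probes kept a shift of 0.6589 after the same scaling (fry unadjusted p = 0.066), so scaling did not remove every difference between these arrays. The test therefore cannot settle this cause. Scan day stayed open, since the pair of arrays that shared a day differed by 0.5615, against 1.45 pooled, and a single pair gives no spread. A difference between the mutations or between the mating-type constructs of the strains stayed open too.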

How the results depend on the processing

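All alternatives on the arrays scanned on the first day, on DNA missing in a strain, GC content, saturation, crossed replicate numbers, processed signals and lncRNA genes were chosen after seeing the data, and the others were planned. The first comparison is the alp13 deletion against wild type, the second clr6-1 against wild type and the third the alp13 deletion against clr6-1. The unchanged settings called 35, 0 and 98 probes, 17, 3 and 13 genes, and 2, 1 and 1 domains in these comparisons. Each gene called in a comparison kept its direction under every alternative that gave it a value of its own (for gene extent, a probe minimum and lncRNA genes only the counts were computed), although many calls were lost. In the first comparison mei4 ran from -1.48 to -0.83 and mcp7 from -1.69 to -0.80, and in the second mei4 ran from -1.93 to -1.24, ssm4 from -1.66 to -1.01 and mcp7 from -1.75 to -0.90. The subtelomere shift stayed positive in the alternatives that gave one, from 0.44 to 1.61 in the first, 0.0066 to 0.98 in the second and 0.33 to 1.55 in the third, but within the shared scan day it was only 0.0256 in the third. The mating-type shift of the second with quantile normalization includes probes without DNA in clr6-1, and without these it was -0.69 and did not pass (fry adjusted p = 0.0587). The cause was not tested for any change listed here. Signal over background, 3.24 to 5.91 in the WCE channel, and 2 arrays per genotype limit the size of difference that can pass. With 1 array left in a genotype, that lone array is assumed to vary like the other groups. Processed signals could be compared in the third comparison only, since wild type files hold none, and a fixed scan day could be fitted there only.

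With normexp background, the first called 0 probes, 4 genes (2 higher, 2 lower) and 8 domains, gave a shift of 1.16 for the islands (fry adjusted p = 0.0557) and turned pho1 to 0.0225 and clr6 to -0.0885. With normexp background, the second called 3 domains and turned spl1 to -0.13 and SPATRNAARG.01 to -0.0102. With normexp background, the third called 28 probes (25 higher, 3 lower) and 5 domains. With loess within arrays, the first called 0 probes, 0 genes and 1 domain, gave shifts of 0.81 for the islands (fry adjusted p = 0.133) and -0.12 for the pNSU clones (fry adjusted p = 0.835) and turned alp13 to 0.64, Tf2-7 to -0.28, Tf2-9 to -0.41, Tf2-11 to -0.38, Tf2-10 to -0.41, ura4 to 0.0753 and clr6 to -0.0814. With loess within arrays, the second called 1 gene and 0 domains. With loess within arrays, the third called 32 probes, 2 genes (2 higher, 0 lower) and 0 domains and turned alp13 to 0.81. With quantile normalization, the first called 20 probes (13 higher, 7 lower), 8 genes (3 higher, 5 lower) and 8 domains, gave shifts of -0.14 for the centromeres (fry adjusted p = 0.101), 0.56 for the islands (fry adjusted p = 0.0714) and -0.45 for the pNSU clones (fry adjusted p = 0.151) and turned clr6 to -0.0471. With quantile normalization, the second called 75 probes, 5 genes and 9 domains, gave shifts of -0.0907 for the centromeres (fry adjusted p = 0.141) and -0.89 for the mating-type region (fry adjusted p = 0.0334) and turned tlh1 to -0.0439 and SPCTRNAVAL.09 to -0.25. With quantile normalization, the third called 230 probes (100 higher, 130 lower) and 7 domains, gave shifts of -0.0509 for the centromeres (fry adjusted p = 0.54) and 1.01 for the mating-type region (fry adjusted p = 0.0203) and turned alp13 to 0.14. After centromere scaling, the first called 7 probes, 31 genes and 8 domains, gave shifts of 0.78 for the subtelomeres (fry adjusted p = 0.0289) and -0.11 for the pNSU clones (fry adjusted p = 0.562) and turned clr6 to -0.0272. After centromere scaling, the second called 20 probes, 6 genes (1 higher, 5 lower), 4 domains and 5 lists in camera. After centromere scaling, the third called 20 genes and 6 domains and gave a shift of 1.11 for the mating-type region (fry adjusted p = 0.0143). After centromere scaling, there was a correlation of 0.35 between the first and second and 4 genes called in both. On the deposited series table, the first called 319 probes and 26 genes and turned alp13 to 0.001. On the deposited series table, the second called 37 probes. On the deposited series table, the third called 221 probes and 2 domains and turned alp13 to 0.13. With outlier spots kept, the first called 16 probes and 1 domain, gave a shift of 1.28 for the islands (fry adjusted p = 0.0531) and turned Tf2-10 to -0.11. With outlier spots kept, the third called 2 domains. Over uniquely matched probes, the first called 5 domains and gave a shift of 1.4967 for the subtelomeres (fry adjusted p = 0.0403). Over uniquely matched probes, the second called 2 probes and 2 domains and gave shifts of 0.0499 for the mating-type region (fry adjusted p = 0.956) and 0.19 for the pNSU clones (fry adjusted p = 0.956). Over uniquely matched probes, the third called 5 domains. Over uniquely matched probes, there were 361 enriched probes in the alp13 deletion, 388 enriched probes in clr6-1 and 145 enriched probes in wild type. With a random scan day, the first called 26 genes. With a fixed scan day, the third called 6337 probes (2594 higher, 3743 lower), 315 genes (109 higher, 206 lower) and 9 domains and turned tlh1 to -0.20. With a trended robust prior, the first called 2 probes (1 higher, 1 lower), 0 genes and 4 domains. With a trended robust prior, the second called 2 probes, 0 genes and 0 domains. With a trended robust prior, the third called 278 probes (80 higher, 198 lower) and 4 domains. Without both day-1 arrays, the first called 816 probes, 56 genes and 19 domains, gave a shift of 1.41 for the islands (fry adjusted p = 0.0979) and turned alp13 to 0.49, ura4 to 0.67 and clr6 to -0.0408. Without both day-1 arrays, the second called 228 probes, 7 genes (4 higher, 3 lower) and 3 domains. Without both day-1 arrays, the third called 956 probes, 60 genes (48 higher, 12 lower) and 19 domains and turned mug9 to -0.0217, hht3 to 0.0021, ura4 to 0.13, ght8 to -0.0798 and alp13 to 0.63. After GC trend removal, the first called 58 probes. After GC trend removal, the third called 4 domains. Scaled, without day-1 arrays, the first called 1 probe, 43 genes and 12 domains, gave shifts of -0.0051 for the centromeres (fry adjusted p = 0.532), 0.71 for the islands (fry adjusted p = 0.122) and -0.31 for the pNSU clones (fry adjusted p = 0.311) and turned alp13 to 0.40, ura4 to 0.41 and clr6 to -0.0975. Scaled, without day-1 arrays, the second called 66 probes, 16 genes (6 higher, 10 lower) and 9 domains and turned tlh1 to -0.0178. Scaled, without day-1 arrays, the third called 40 genes and 11 domains, gave a shift of -0.0521 for the centromeres (fry adjusted p = 0.292) and turned hht3 to 0.065 and alp13 to 0.57. Without saturated probes, the second called 2 domains. Scaled on unsaturated probes, the first called 8 probes, 31 genes and 7 domains, gave a shift of -0.0967 for the pNSU clones (fry adjusted p = 0.557) and turned clr6 to -0.0238. Scaled on unsaturated probes, the second called 20 probes, 5 genes and 4 domains and gave a shift of -0.0522 for the centromeres (fry adjusted p = 0.629). Scaled on unsaturated probes, the third called 21 genes and 5 domains and gave a shift of 1.18 for the mating-type region (fry adjusted p = 0.0237). Scaled, without no-DNA probes, the first called 0 probes, 31 genes and 8 domains, gave shifts of 0.78 for the subtelomeres (fry adjusted p = 0.0289) and -0.11 for the pNSU clones (fry adjusted p = 0.562) and turned clr6 to -0.0272. Scaled, without no-DNA probes, the second called 12 probes, 7 genes (2 higher, 5 lower) and 5 domains. Scaled, without no-DNA probes, the third called 21 genes and 6 domains and gave a shift of 0.94 for the mating-type region (fry adjusted p = 0.0276). On Feature Extraction processed signals, the third called 1 probe (1 higher, 0 lower) and 2 genes (2 higher, 0 lower) and turned Tf2-7 to -0.12, Tf2-11 to -0.16, Tf2-9 to -0.30, Tf2-10 to -0.21 and alp13 to 0.42. Scaled, without any no-DNA probe, the third gave a shift of 0.91 for the mating-type region (fry adjusted p = 0.0327). With quantile normalization and without any no-DNA probe, the third gave a shift of 0.80 for the mating-type region (fry adjusted p = 0.0349). At a 3-fold threshold, there were 555 enriched probes in clr6-1. With upstream sequence added, the second called 1 gene. With upstream sequence added, the third called 32 genes (12 higher, 20 lower). With lncRNA genes included, the first called 1 gene (1 higher, 0 lower). With lncRNA genes included, the second called 0 genes. With runs of at least 5 probes, there were 3 WCE runs.

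Leaving out each array in turn, the first called probes 0 to 206, genes 0 to 40, domains 1 to 16 and lists in camera 1 to 7. Class shifts that changed sign or call and genes that changed sign in the first ran over island shift 1.17 to 1.41, alp13 -1.11 to 0.49, ura4 -2.23 to 0.67, his2 -0.0892 to 0.54, str3 -0.43 to 0.0105 and clr6 -0.12 to 0.15. Leaving out each array in turn, the second called probes 0 to 100, genes 0 to 30 and domains 0 to 9. Class shifts that changed sign or call and genes that changed sign in the second ran over mating-type region shift -0.58 to 0.0798, pNSU clone shift -0.23 to 0.12, str3 -0.0073 to 0.43 and clr6 -0.21 to 0.0526. Leaving out each array in turn, the third called probes 38 to 653, genes 8 to 71 and domains 0 to 12. Class shifts that changed sign or call and genes that changed sign in the third ran over centromere shift -0.14 to 0.91, cph1 -0.40 to 0.10, mug9 -0.0658 to 1.09, ght8 -0.0471 to 0.38 and alp13 -0.92 to 0.68. The same omissions gave 435 to 1393 enriched probes in clr6-1, 344 to 581 enriched probes in wild type, a correlation of 0.17 to 0.53 between the first and second and 0 to 17 genes called in both. Either wild type array left out gave 0, 0 and 8 genes in the 3 comparisons. All 17 genes of the first and all 3 of the second lost their call in some omission, as did 6 of the 13 of the third, where 7 kept it in each (SPAC186.03, SPAC186.07C, SPAC186.08C, SPAC750.01, SPAC977.14C, pdc102 and snR41). Without the second alp13 deletion array the first called 34 genes (12 higher, 22 lower) and 111 probes (14 higher, 97 lower), and the third 71 genes (13 higher, 58 lower) and 653 probes (102 higher, 551 lower). Without the first clr6-1 array the third called 16 genes (7 higher, 9 lower) and 133 probes (47 higher, 86 lower), and without the second clr6-1 array the second called 0 genes. The fixed scan day rests on the single pair of arrays that shared a day, with the spread taken from the wild type arrays. With 1 array left out fry called 0 to 3 lists in the first, 0 to 2 in the second and 0 to 2 in the third, against 4, 4 and 3 with all arrays, and after centromere scaling 1, 1 and 0. camera with an estimated correlation called 0 lists in each comparison, against 3, 3 and 2 with the preset one.

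The replicate number as a block called 287 probes, 46 genes and 20 domains in the first comparison, 18, 4 and 14 in the second, and 310 (137 higher, 173 lower), 29 and 9 in the third. With it the island shift of the first was 1.29 (fry adjusted p = 0.0550). The second then had 1 gene higher and 3 lower. Replicate deviations from the group means correlated at -0.11 between the mutants, -0.0045 between the alp13 deletion and wild type and 0.0081 between clr6-1 and wild type, so the arrays share only a number and are not paired by it. With the clr6-1 numbers crossed, the first called 132 probes, 24 genes (18 higher, 6 lower) and 1 domain, the second 40 probes, 3 genes and 0 domains, and the third 280 probes (119 higher, 161 lower), 21 genes (10 higher, 11 lower) and 0 domains, and the island shift of the first had a fry adjusted p of 0.178.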

Other observations

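The tests of this part, on small RNA genes and on ura4, were all chosen after the result was seen. The tests on small RNA genes used those measured on all 6 arrays, 43 small nucleolar RNA genes and 18 5S rRNA genes. Over all 50 small nucleolar RNA genes the median difference was -0.26 between the alp13 deletion and wild type (camera with an estimated correlation, adjusted p = 0.0419), -0.0044 between clr6-1 and wild type (adjusted p = 0.629) and -0.19 between the alp13 deletion and clr6-1 (adjusted p = 0.0422). Over all 21 5S rRNA genes the medians were -0.09, 0.37 and -0.19 (adjusted p = 0.629, 0.129 and 0.129). Over 61 mitochondrial probes the mean log2 ratio was 0.23 ± 0.03 (SD, n = 2) in the alp13 deletion, -0.42 ± 0.34 in clr6-1 and -0.42 ± 0.06 in wild type.

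The ura4 probes gave a WCE signal of 181% ± 2.90 (SD, n = 2) of the array median in clr6-1, 76.4% ± 5.51 in wild type and 10.1% ± 6.04 in the alp13 deletion, and the ratio at ura4 in clr6-1 was 1.31 ± 0.68 (SD, n = 2). A ura4 copy placed in the deleted mating-type stretch of clr6-1 could account for this. The WCE signal of ura4 was higher in clr6-1 than in wild type by 1.3556 (log2), which that hypothesis needs, but no probe spans a junction, so whether an additional copy exists, and where, stayed open.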
